A study of Homo sapiens with 27 samples.

How the data were processed

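The samples were 27 miRNA arrays of total RNA from OCI-AML3 cells: 3 untreated controls at 0 h, and 3 arrays for each of SDF-1α (100 ng/mL) and POL6326 (250 nM) at 1, 2, 4 and 8 h. Per the labels, the RNA was reverse transcribed with a biotin-labelled primer carrying a random end, and the product was hybridised to a chip. The deposited table holds log2 signals for 784 probes, of which 774 are human miRNA probes and 10 are control probes for transfer RNAs and other transcripts. The scanner software, the background correction and the normalization are not given in the sources used here. The 27 columns share 1 maximum value, as after a quantile normalization, and each has a block of tied low values, its floor, with 1 to 39 values under it. No column was left without a sample. Of the 774 probes, 637 were for mature miRNAs, 137 for precursors, and 38 carried the mark "Plus/Minus", whose meaning the sources used here do not give. The root names of 715 probes matched a synonym among 1913 miRNA genes of the RefSeq table, 59 did not, and all were kept under the name in the deposited table. No genome build is named, so no positions are given.

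The deposited values were used as they stand. The floor was taken as an array's most frequent value, a probe at or under it was counted as at the floor, and the detection limit was taken as the lowest value above it, with a tolerance of 1e-04. Where all arrays of 1 group were at the floor, the fold was taken from the other group's mean against the mean of that group's detection limits and is printed as "at least". A fitted log2 change that includes arrays at the floor depends on where that floor lies, and so do its SE and p-value. Tied floor values vary little within a group, so that SE and p-value can be too small. The number of probes above the floor (210 to 593 per array) gives the depth.

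A model with 1 mean for each of the 9 groups was fitted to all 27 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (prior degrees of freedom 0.90). Each treated group was compared with control, POL6326 with SDF-1α at each time, and the equal-weight means of 4 times with each other and with control. Moderated F-tests covered the change over time within each treatment and the treatment by time interaction. P-values are two-sided and adjusted by Benjamini-Hochberg over the 774 probes within each comparison, with the threshold at an adjusted p of 0.05. Control probes were left out of these tests and examined apart. With 3 arrays per group, 10 splits are possible and the smallest exact permutation p is 0.1, so single-time calls rest on the model that pools the spread over groups.

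Named probes were chosen by a rule written before the data were examined, as were the comparisons, lists and alternatives not marked below as added. The rule took the 12 largest rises and 12 largest falls past the threshold in each comparison of means, 5 and 5 at each single time, the 5 smallest p in each F-test, every let-7 family probe, and up to 4 members of each other list with the smallest p. The lists, matched by miRNA name, were the let-7 family, miR-17 family and clusters, miR-15 and miR-16 family, miR-29 family, p53-linked, HOX-embedded, NF-kB-linked inflammatory, myeloid and haematopoietic, stem-cell and leukaemia-linked, hypoxia, erythroid, muscle, liver, neural, epithelial, stromal and endothelial, pluripotent, C19MC and the DLK1-DIO3 cluster. Probes of miR-125b, miR-126, miR-128a, miR-128b, miR-155, miR-424 and miR-9 are in more than 1 list. Lists of at least 3 probes were tested with camera (preset correlation 0.01, and an estimated correlation beside it) and fry, adjusted over 17 lists. The overlap of the calls against the shared control was set beside 100 simulations of unchanged groups.

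The alternatives were median centring, quantile normalization, the upper 50% of probes by mean signal, leaving out probes at the floor on over 50% of arrays, averaging probes of 1 miRNA, moderation with a trend and robust prior, a replicate block, fitting only the groups compared, an absolute log2 change of at least 0.58, and leaving out each array in turn. Added after seeing the data were 1 common detection limit (7.42, the highest of the 27, with 276 probes above it on at least 3 arrays), the number of probes above the floor as a covariate, and leaving out the 1 h or the 4 h arrays, and raising values under the floor to it. The 1 h or 4 h arrays were left out of the means and time tests, but stayed in the estimate of the spread. The number of probes above the floor differs between the groups, so fitting it as a covariate can also remove part of a treatment effect. Splits of the samples other than the real one were also counted, up to 100 per comparison.

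The scripts were tested on simulated data in which 67 or 66 probes changed by a log2 of 0.58, 1 or 2. All of these sets changed in the same data, and the noise was independent between probes. For POL6326 against SDF-1α over 4 times this gave 153 calls, against 76 in the real data. With fewer probes changed, recovery can be lower and the share of unchanged calls higher than the values below. With values floored as on these arrays, limma recovered 44.8%, 70.1% and 89.4% of them for POL6326 against SDF-1α over 4 times, 20.9%, 49.3% and 77.3% for SDF-1α against control over 4 times, and 22.4%, 44.8% and 77.3% for POL6326 against control. At single times it recovered 62.1% of changes of 2 for SDF-1α against control at 2 h and 56.1% for POL6326 against SDF-1α at 4 h, and 39.4% for the interaction. A test first set to require recovery of over 50% at a change of 2 was not met by the interaction and was replaced by a test on the size of the estimates. Unchanged probes made up 11.1% of the simulated calls for POL6326 against SDF-1α over 4 times, 29.3% at 4 h and 24.2% for the interaction, above the nominal rate. At 4 h, 5.76% of the unchanged dim probes and 1.43% of the unchanged measured probes were called, and for the interaction 2.53% and 2.86%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.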

Results

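MicroRNA (miRNA) signals were measured on 27 arrays of RNA from OCI-AML3, an acute myeloid leukaemia cell line. The control cells were untreated and taken at 0 h. The other cells received 100 ng/mL SDF-1α, the chemokine that binds and activates the receptor CXCR4, or 250 nM POL6326, a CXCR4 antagonist, and were taken at 1, 2, 4 and 8 h. This gave 9 groups of 3 arrays. The labels do not say whether the 3 arrays of a group came from separate cultures, so every p-value here measures the spread between these arrays. The control was taken at 0 h alone, so a difference from it mixes the treatment with time in culture, whereas POL6326 and SDF-1α were compared at matched times. The title of the series places let-7a downstream of CXCR4, and the comparison of antagonist with ligand asks which miRNAs differ between blocking and activating that receptor.

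Each array had a block of tied low values, called its floor here, at a log2 signal between 4.27 and 4.43. Over the 27 arrays 10816 values were tied at the floor and 299 lay under it, by up to 3.28, and both kinds are counted as at the floor. The lowest value above the floor is called the array's detection limit. Of 774 miRNA probes, 174 were above the floor on all 27 arrays and 99 were at the floor on all of them. The mean number of probes above the floor was 374 ± 163 (SD, n = 3) in control, where the arrays ranged from 257 to 560. With SDF-1α it was 223 ± 16.3 at 1 h, 325 ± 7.64 at 2 h, 371 ± 9.61 at 4 h and 391 ± 88.6 at 8 h (SD, n = 3 each). With POL6326 it was 326 ± 8.02 at 1 h, 324 ± 7.94 at 2 h, 525 ± 59.8 at 4 h and 403 ± 16.5 at 8 h (SD, n = 3 each). The detection limit was highest on the SDF-1α 1 h arrays (6.88 to 7.42) and lowest on the POL6326 4 h arrays (4.27 to 4.45). Where all arrays of one group were at the floor, the difference is given as a bound against the mean of that group's detection limits. The number of arrays limits the precision.

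**Figure D1:**
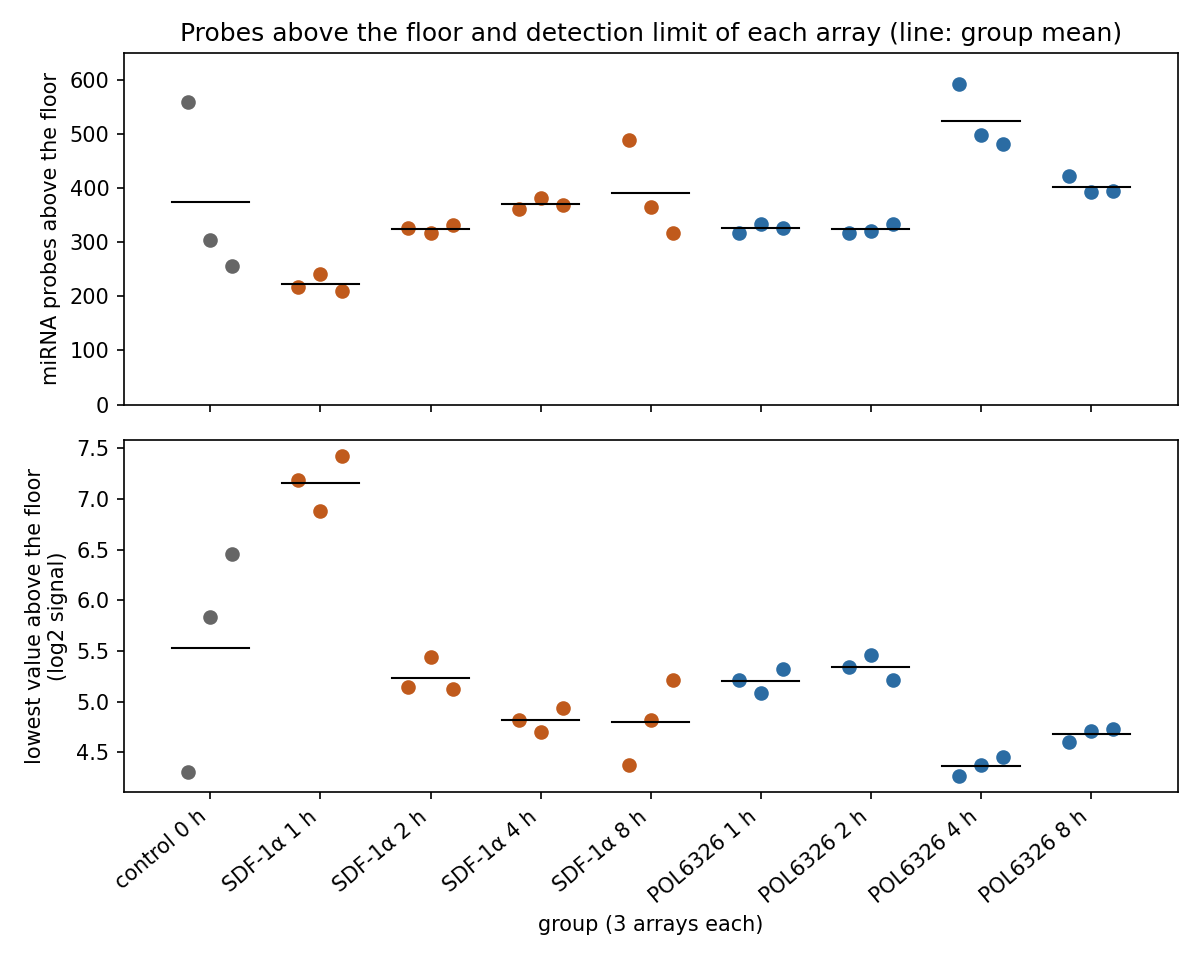
Number of miRNA probes above the floor (top) and detection limit on the log2 scale (bottom) of each of the 27 arrays, by group, with lines at the group means. The 3 SDF-1α 1 h arrays measured 210 to 241 probes, and the 3 POL6326 4 h arrays measured 482 to 593.

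The mature let-7a probe, a miRNA of the let-7 family of tumour suppressors, read 7.86 ± 0.36 (SD, n = 12) on the log2 scale with POL6326 and 6.07 ± 1.41 (SD, n = 12) with SDF-1α over the 4 times. The fitted log2 difference, POL6326 minus SDF-1α, was 1.79 (SE 0.40, 3.46-fold, adjusted p = 0.00717 by limma's moderated test). let-7a was above the floor on 12 of 12 POL6326 arrays and 8 of 12 SDF-1α arrays, so this size depends on where the floor lies. At 1 h all 3 SDF-1α arrays were at or under the floor, and let-7a was at least 1.60-fold higher with POL6326 (adjusted p = 0.0199). The log2 differences at 2, 4 and 8 h were 1.00, 0.77 and 1.91 (SE 0.80 each), with adjusted p of 0.749, 0.597 and 0.409. Against the control (6.90 ± 2.20, SD, n = 3, with 1 array at the floor), let-7a differed by -0.83 (SE 0.63, adjusted p = 0.727) with SDF-1α and by 0.96 (SE 0.63, adjusted p = 0.546) with POL6326, and neither passed the threshold. The let-7a call between the treatments ended without the 1 h arrays (log2 1.22, SE 0.46, adjusted p = 0.125) and with the number of probes above the floor as a covariate (log2 1.25, adjusted p = 0.0878). With 1 detection limit for all arrays it was 0.38 (adjusted p = 0.0271), and over all alternatives adjusted p ranged from 0.000682 to 0.125.

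**Figure D2:**
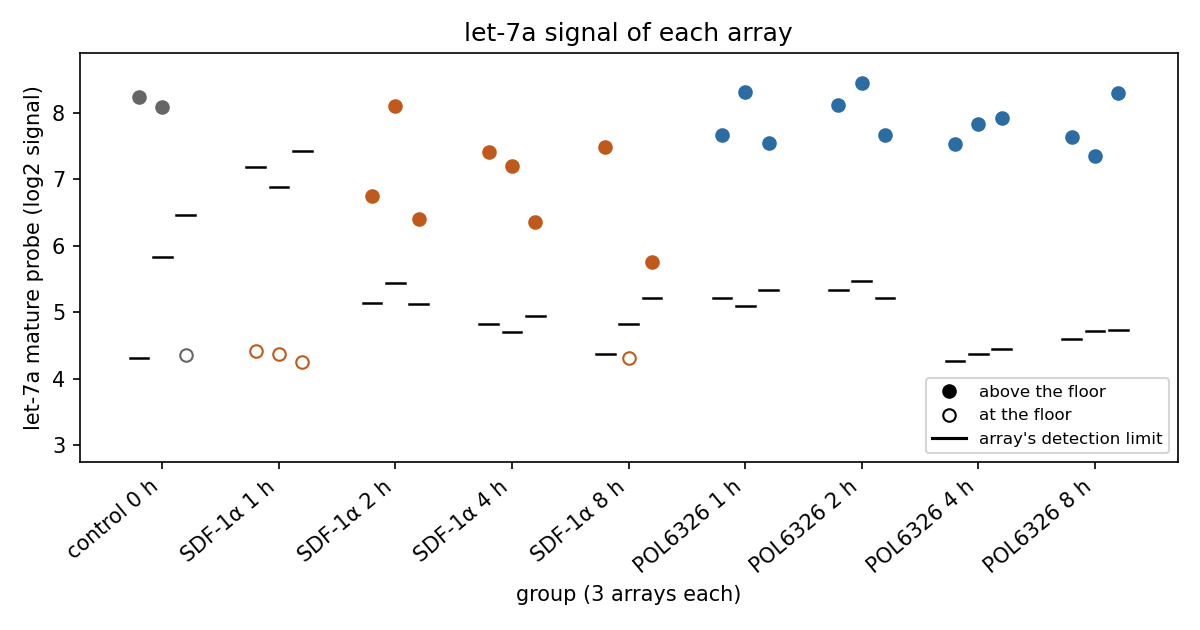
Log2 signal of the mature let-7a probe on each array, by group; filled points are above the array's floor, open points are at or under it, and short lines mark each array's detection limit. All 12 POL6326 arrays are above the floor, and the 3 SDF-1α 1 h arrays are not, under detection limits of 6.88 to 7.42.

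The let-7 family as a whole had 17 probes. Between POL6326 and SDF-1α, let-7a was the 1 member past the threshold, both over all probes and adjusted over the list alone. Other members included let-7c at 0.70 (adjusted p = 0.141), let-7f at 0.66 (adjusted p = 0.256) and let-7g at 0.04 (adjusted p = 0.957). The star strand let-7a* was at the floor on 25 of 27 arrays. Against the control, let-7i rose 1.64-fold with POL6326 (log2 0.71, SE 0.18, adjusted p = 0.0252), a call lost with median centring, without the 1 h arrays and without control array 2 (adjusted p = 0.187). It was the 1 of 17 probes past the threshold there, and 0 of 17 passed with SDF-1α, where let-7i passed when adjusted over the list alone. The family's median log2 difference was 0.09 between the treatments, 0.07 for POL6326 against control and 0.01 for SDF-1α against control. Camera gave adjusted p of 0.207, 0.555 and 0.946 (0.523, 0.712 and 0.962 with an estimated correlation). With median centring the median turned to -0.05 between the treatments and -0.01 for POL6326 against control. The title of the series names let-7a, and the labels do not say whether it was chosen on these samples, so the family's direction is not taken as independent evidence.

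Between POL6326 and SDF-1α over the 4 times, miR-136*, from the DLK1-DIO3 cluster, was 4.75-fold higher with POL6326, at 11.95 ± 0.59 against 9.70 ± 1.02 (SD, n = 12 each; log2 2.25, SE 0.22, adjusted p = 2.11e-06). The mature miR-138 probe was above the floor on 12 of 12 POL6326 arrays and 4 of 12 SDF-1α arrays, with a log2 difference of 3.31 (SE 0.53, adjusted p = 0.00046). miR-579 was higher by 2.76 (SE 0.40) and miR-451, a miRNA of red-cell precursors, by 1.76 (SE 0.22). They were at the floor on 7 and 8 of 12 SDF-1α arrays, so these sizes, like that of miR-138, depend on where the floor lies. miR-572 fell by 1.73 (SE 0.30), from 9.82 ± 1.53 to 8.09 ± 0.98 (SD, n = 12 each), which is 3.31-fold lower with POL6326. By time it differed by -2.13, -3.66, -0.23 and -0.89 at 1, 2, 4 and 8 h, and passed at 2 h alone. Of the miR-181 family, which acts in blood-cell development and was not tested as a list of its own, 3 named probes passed, in both directions. miR-181b was 1.65 higher, miR-181a-2* was 2.64-fold lower (log2 -1.40, SE 0.25, adjusted p = 0.00119) and miR-181c* was 1.62-fold lower (log2 -0.69, SE 0.11, adjusted p = 0.00046). miR-181b was at the floor on 10 of 12 SDF-1α arrays and passed at 0 of 4 single times.

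In all, 76 of 774 probes differed between POL6326 and SDF-1α by limma's moderated test, 42 higher and 34 lower with POL6326. The balance of directions depended on the setting: 44 were higher and 266 lower with median centring, 31 and 49 with 1 detection limit for all arrays, 30 and 9 with the number of probes above the floor as a covariate, and 39 and 14 at an absolute log2 change of at least 0.58. An unadjusted p under 0.05 was reached by 155. Of the 76 probes, 40 were above the floor on all 27 arrays, 49 had 1 sign at all 4 times and 59 passed at 1 or more single times. The others among the 12 largest rises were the precursors of miR-600 (2.08), miR-638 (1.96) and miR-376b (1.89), and miR-506 (1.89), miR-126* (1.81), let-7a, miR-608 (1.71) and miR-181b. Of the 12 rises, miR-136* alone was above the floor on all SDF-1α arrays, and the others were at it on 4 to 10 of 12. The others among the 12 largest falls were miR-424 (-1.34), the miR-611 precursor (-1.22), miR-560 (-1.01), the miR-631 precursor (-0.83), miR-24 (-0.79), miR-635 (-0.76), miR-16 (-0.75), miR-565 (-0.74) and its precursor (-0.70). Without the 4 h arrays, where the POL6326 arrays had low detection limits, 44 probes passed, 35 of them among the 76, and with the number of probes above the floor as a covariate 39 passed, 27 of them among the 76. Of the 24 named probes, miR-138, miR-579, miR-136*, the miR-638 precursor, miR-572, miR-181a-2* and miR-181c* stayed past the threshold under every alternative run and without any 1 array, whereas none of the other falls did.

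**Figure D3:**
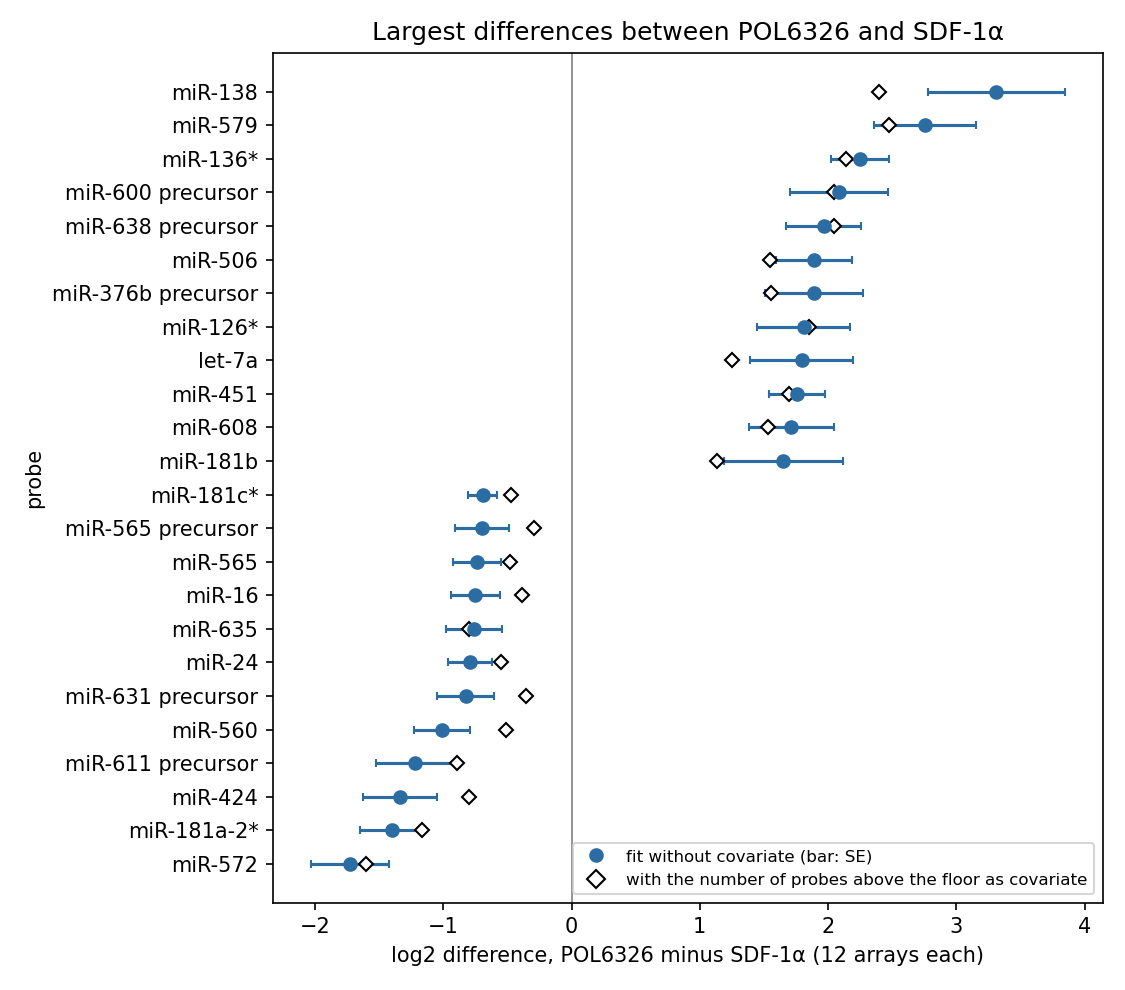
Log2 difference between POL6326 and SDF-1α, mean of 4 times, for the 12 largest rises and 12 largest falls among the probes past the threshold (filled points, bars are SE, 12 arrays per treatment), and the value with the number of probes above the floor as a covariate (open diamonds). miR-138 moves from 3.31 to 2.40 and miR-424 from -1.34 to -0.80 with the covariate.

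By list, the DLK1-DIO3 cluster (75 probes) had 6 members higher and 1 lower with POL6326, with miR-136* and the miR-376b precursor joined by miR-758 (1.18, SE 0.17) and miR-494 (1.16, SE 0.27). The mean for miR-758 rests on 1 h, when it was at the floor on the SDF-1α arrays: at 2, 4 and 8 h it differed by 0.16, 0.21 and 0.10 (SE 0.34 each; adjusted p = 0.995, 0.784 and 1). Of 28 myeloid and haematopoietic probes, miR-181b was higher, and miR-181a-2*, miR-181c*, miR-424 and miR-24 were lower. Of 13 probes of the miR-15 and miR-16 family, which restrains the cell cycle, miR-424 and miR-16 were lower and 11 did not pass. Of 11 probes embedded in the HOX gene clusters, miR-196b (-0.51, SE 0.16) and the miR-196a-1 precursor (-0.36, SE 0.11) were lower. miR-196b was above the floor on 8 of 27 arrays, and its mean rests on 2 h (-2.37), against 0.27, -0.35 and 0.41 at 1, 4 and 8 h (adjusted p = 0.713, 0.512 and 0.827). Its SDF-1α mean of 5.03 lay under the mean limit (5.04) of the 8 POL6326 arrays at the floor, so the size of its mean difference is not shown. Of 16 NF-kB-linked inflammatory probes, miR-125b-2* (1.50, SE 0.14), miR-146a (1.59, SE 0.29) and miR-9 (1.35, SE 0.37) were higher. These sizes depend on where the floor lies, as the 3 probes were at it on 3, 10 and 3 of 12 SDF-1α arrays. The POL6326 mean of miR-125b-2* (6.94) lay under the mean limit (7.16) of those SDF-1α arrays. By time, miR-125b-2* was lower at 4 h (-1.04), miR-146a passed at 2 h alone and stood at -0.17 at 8 h, and miR-9 passed at 1 h alone, with the SDF-1α arrays at the floor, and differed by 0.84, 0.47 and 0.53 later. The stem-cell and leukaemia-linked list (18 probes) had miR-125b-2* and miR-126* higher. The miR-17 family and clusters (27 probes), which hold proliferation-linked miRNAs, had miR-92a higher (0.70, SE 0.18) and miR-92b* lower (-0.59, SE 0.16). The miR-29 family (7 probes) had miR-29b-2* higher (1.40, SE 0.44), the p53-linked list (17 probes) had miR-34c-3p lower (-0.22, SE 0.07), and the erythroid list (5 probes) had miR-451 higher. miR-29b-2* was at the floor on 5 of 12 SDF-1α arrays and passed at 0 of 4 single times. The hypoxia miRNA miR-210 stood at -0.07.

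Among lists for cell types that an AML line should lack, the neural list (18 probes) had miR-138, the Plus/Minus probe of miR-138-1* (0.66, SE 0.08) and miR-9 higher and the other miR-138-1* probe lower (-0.25, SE 0.06). The epithelial list (11 probes) had miR-203 (1.41, SE 0.26) and miR-200a* (resting on 8 h) higher, the stromal and endothelial list (14 probes) had miR-126* and miR-214 (0.26, SE 0.07) higher, and the muscle list (13 probes) had miR-133b higher (1.41, SE 0.36). miR-203 was at the floor on 9 of 12 SDF-1α arrays, so its size depends on where the floor lies. The POL6326 mean of miR-203 was 6.01, against a mean limit of 5.80 on those arrays. miR-200a* was at the floor on 11 of 12 SDF-1α arrays. Its POL6326 mean of 4.74 lay under their mean detection limit (5.61), so no size is given for the mean of 4 times. The pluripotent list (16 probes) had miR-373* lower (-0.24, SE 0.07), C19MC (50 probes) had 0 calls in either direction, and the 2 liver probes had a median of -0.24 and 0 calls. Adjusted over the list alone, the miR-15 and miR-16 family and the HOX-embedded list had 4 lower each, the myeloid list had 3 higher and 4 lower, the epithelial and stromal lists had 3 higher each, the p53-linked and pluripotent lists had 0, and the other lists had the counts given above.

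Camera put 0 of 17 lists past the threshold between the treatments (lowest adjusted p = 0.207, and 0.499 with an estimated correlation). Fry, which asks whether a list moves 1 way on balance, put 3 past it: the miR-15 and miR-16 family lower (median -0.11, adjusted p = 0.0187), the HOX-embedded list lower (median -0.24, adjusted p = 0.0187) and the NF-kB-linked list higher (median 0.05, adjusted p = 0.0415). With the covariate these became 0.082, 0.186 and 0.186, and with median centring the NF-kB-linked median turned to -0.10. With median centring fry put 10 of 17 lists past the threshold, all lower, and camera put C19MC past it (lower, adjusted p = 0.0205). The medians of the neural, muscle, epithelial, erythroid, stem-cell, myeloid, C19MC and DLK1-DIO3 lists were negative where their means were positive. For the erythroid, C19MC and DLK1-DIO3 lists the median (-0.03) is the difference of a probe at the floor on all arrays, such as miR-217.

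At single times, POL6326 and SDF-1α differed in 27 probes at 1 h (24 higher and 3 lower with POL6326), 32 at 2 h (16 and 16), 76 at 4 h (29 and 47) and 8 at 8 h (6 and 2). At an unadjusted p under 0.05 the counts were 206, 102, 176 and 82. At 1 h, where all 3 SDF-1α arrays were at the floor for them, miR-758 was at least 2.80-fold, miR-138 at least 2.31-fold, miR-125b-2* at least 1.72-fold, the miR-657 precursor at least 1.70-fold and miR-9 at least 1.66-fold higher with POL6326. The 3 falls at 1 h were miR-30c-1* (-2.81, SE 0.73), the miR-619 precursor (-1.21, SE 0.32) and miR-34c-3p (-0.57, SE 0.13). At 2 h miR-138 was at least 11.2-fold, miR-146a at least 6.08-fold and miR-590-5p at least 4.35-fold higher, with miR-126* (3.27, SE 0.72) and miR-451 (3.10, SE 0.43) also higher. miR-196a was at least 3.92-fold and miR-196b at least 2.60-fold lower at 2 h, with miR-572 (-3.66, SE 0.61), miR-374b* (-3.23, SE 0.83) and miR-15b (-2.69, SE 0.59). At 4 h the miR-376b precursor was at least 9.07-fold, miR-551b* at least 9.06-fold and miR-548c-3p at least 6.86-fold higher, with miR-138 (4.02, SE 1.07) and miR-579 (3.84, SE 0.79), and the largest falls were miR-10b* (-2.91, SE 0.85), miR-195 (-2.77, SE 0.81), miR-181a-2* (-2.59, SE 0.50), the Plus/Minus probe of miR-409-3p (-2.51, SE 0.62) and miR-424 (-2.49, SE 0.57). At 8 h the miR-638 precursor (3.20, SE 0.59), miR-136* (2.60, SE 0.45), miR-203 (2.48, SE 0.52), miR-125b-2* (1.70, SE 0.28) and miR-200a* (1.14, SE 0.19) were the largest rises, miR-328 fell by 0.86 (SE 0.15), and miR-652 was at least 1.50-fold lower. At 2 h miR-126* and miR-451, and at 4 h miR-138, had 2 of 3 SDF-1α arrays at the floor. So had miR-203 and miR-200a* at 8 h. On 1 of 3 SDF-1α arrays miR-579 (4 h) and the miR-638 precursor (8 h) were at it. For the falls of miR-30c-1* (1 h) and miR-15b (2 h), 2 of 3 POL6326 arrays were at the floor. All of these sizes depend on where the floor lies. With 1 detection limit for all arrays 24 probes passed at 1 h, 10 of them among the 27. The share of higher probes among the calls was then 41.7%, against 88.9% without that limit (87.5% with the covariate). With the covariate 9 probes passed at 4 h, 8 of them among the 76. With median centring, 23 were higher and 295 lower at 4 h, and 8 and 200 at 8 h. At 8 h limma called 0 when only the groups compared were fitted, against 82 at an unadjusted p under 0.05 with all groups. Without POL6326 4 h array 1 the 4 h count was 26, and without SDF-1α 1 h array 3 the 1 h count was 11.

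Against the 0 h control, where treatment and time in culture cannot be told apart, miR-30c was 1.74-fold lower with SDF-1α over the 4 times, from 11.06 ± 0.07 (SD, n = 3) to 10.27 ± 0.17 (SD, n = 12; log2 -0.80, SE 0.11, adjusted p = 0.000965). miR-128a, listed as leukaemia-linked and neural, fell by 0.96 (SE 0.18), and miR-10a, which lies in a HOX cluster, fell by 1.13 (SE 0.26). The miR-433 precursor, from the DLK1-DIO3 cluster, rose 4.07-fold, from 6.20 ± 1.11 (SD, n = 3) to 8.22 ± 0.41 (SD, n = 12; log2 2.02, SE 0.38, adjusted p = 0.00588). miR-221, a proliferation-linked miRNA, fell by 1.49 (SE 0.40), and miR-17 fell by 0.74 (SE 0.19).

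In all, 22 probes differed between SDF-1α and control, 7 higher and 15 lower with SDF-1α (108 at an unadjusted p under 0.05). With quantile normalization 13 were higher and 9 lower, and without the 1 h arrays 6 and 5. The other rises were the miR-611 precursor (1.91), miR-125b-2* (0.98, with its mean of 5.43 under the limits of the 2 control arrays at the floor), miR-483-3p (0.92), the miR-650 precursor (0.64), miR-497 (0.46) and the miR-431 precursor (0.38). The largest other falls were miR-146b-5p (-2.34), the miR-646 precursor (-2.23), miR-345 (-2.12), miR-15b (-1.90), the miR-194-1 precursor (-1.30) and miR-425 (-1.27). In that order, all but miR-425 were at the floor on 7, 7, 11, 3 and 10 of 12 SDF-1α arrays, so their sizes depend on where the floor lies. For the miR-194-1 precursor the control mean (5.70) hardly exceeded the mean limit of those arrays (5.69). miR-585 was at the floor on all 12 SDF-1α arrays, and its control mean of 5.38 lay under their mean detection limit (5.50), so no fold is given. By list, the DLK1-DIO3 cluster had 2 higher, the NF-kB-linked, stem-cell and miR-15 and miR-16 lists had 1 higher and 1 lower each, the miR-17, p53-linked, HOX-embedded, myeloid, neural and stromal lists had 1 lower each, and 0 passed in the other lists. Adjusted over the list alone, the neural list had 2 higher and 2 lower, the let-7 and liver lists 1 higher each, and the NF-kB-linked and stem-cell lists 1 higher and 2 lower each, with the other lists as before. Camera put 0 of 17 lists past the threshold (lowest adjusted p = 0.186, and 0.247 with an estimated correlation), and fry 0 (lowest 0.182). These calls rest on the 3 control arrays: without control array 2, 3 probes passed, without control array 3, 38 passed, and of the 19 named probes miR-30c alone stayed past the threshold without each 1 array in turn (highest adjusted p = 0.0085). Without the 1 h arrays 11 probes passed, 9 of them among the 22, and miR-221, miR-17 and miR-10a were then lost. With values under the floor raised to it miR-221 and miR-497 were lost (adjusted p = 0.0508 each).

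At single times, SDF-1α and control differed in 30 probes at 1 h (5 higher, 25 lower with SDF-1α), 20 at 2 h (12 and 8), 15 at 4 h (7 and 8) and 17 at 8 h (3 and 14), with 223, 112, 81 and 101 at an unadjusted p under 0.05. At 1 h miR-570 was at least 2.76-fold, miR-758 at least 2.65-fold, miR-15b at least 2.49-fold and miR-100 at least 1.69-fold lower, with all 3 SDF-1α arrays at the floor, and miR-423-3p fell by 3.29 (SE 0.81). That size depends on the floor too: 2 of 3 SDF-1α arrays were at it for miR-423-3p, with a mean limit of 7.15 against 8.76 in control. Rises at 1 h were the precursors of miR-611 (2.52, SE 0.61), miR-433 (1.87, SE 0.48), miR-650 (0.97, SE 0.22) and miR-431 (0.57, SE 0.13), and miR-483-3p (0.97, SE 0.25). At 2 h miR-196b was at least 2.28-fold higher and the miR-646 precursor at least 4.66-fold lower. miR-137 (2.44, SE 0.55) and miR-561 (1.86, SE 0.43) were higher, and miR-543 fell by 1.02 (SE 0.25). Both higher probes were at the floor on 2 of 3 control arrays, so their sizes depend on where the floor lies. The miR-561 mean of 6.22 lay under the highest limit of those control arrays (6.45). At 4 h miR-380* (2.31, SE 0.31) and miR-125b-2* (1.57, SE 0.28) were higher, each with 2 of 3 control arrays at the floor, and miR-572 (-2.59, SE 0.61) and the miR-206 precursor (-1.64, SE 0.36) fell. At 8 h miR-635 rose by 1.73 (SE 0.43), and miR-221 (-2.16, SE 0.51), miR-140-3p (-2.06, SE 0.42) and miR-106a (-1.51, SE 0.35) fell. miR-652 passed too, but its mean of 5.27 lay under the limits of the 2 control arrays at the floor (mean 6.14), so no size is given. miR-125b-2* at 4 h (6.03) lay under that mean as well. With the covariate 9 probes passed at 1 h and 31 at 8 h. The excess of falls depended on the setting: at 1 h 14 were higher and 22 lower with quantile normalization, and 17 and 27 with 1 detection limit for all arrays, and at 8 h 8 and 9 with quantile normalization and 14 and 17 with the covariate. At 2 h, where rises led, 11 were higher and 19 lower with 1 detection limit for all arrays. With values under the floor raised to it, 127 were higher and 51 lower at 1 h, and 117 of these 178 probes were at the floor on over 50% of arrays. Fitted on the compared groups alone, limma called 2 at 4 h and 0 at 8 h, against 81 and 101 at an unadjusted p under 0.05 with all groups. The 1 h count was 7 without control array 2 and 153 without control array 3, the 2 h count was 1 without SDF-1α 2 h array 2, and the 8 h count was 33 without SDF-1α 8 h array 1.

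Against the 0 h control, where treatment and time in culture cannot be told apart, miR-125b-2* was higher with POL6326 across the 4 times, at 6.94 ± 1.21 (SD, n = 12, all above the floor; fitted log2 difference 2.48, SE 0.22, adjusted p = 7.3e-07). It was at the floor on 2 of 3 control arrays, whose detection limits averaged 6.14, so no fold is given. miR-30c fell 2.02-fold (log2 -1.01, SE 0.11, adjusted p = 1.43e-05) and miR-30b 2.20-fold (log2 -1.14, SE 0.19, adjusted p = 0.00142). miR-572 fell 6.51-fold, from 10.79 ± 0.36 (SD, n = 3) to 8.09 ± 0.98 (SD, n = 12; log2 -2.70, SE 0.48, adjusted p = 0.00269). miR-15b fell by 2.38 (SE 0.47) and miR-10a by 1.37 (SE 0.26). miR-451 rose by 1.83 (SE 0.34) and miR-136* by 1.44 (SE 0.36).

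In all, 29 probes differed between POL6326 and control, 14 higher and 15 lower with POL6326 (117 at an unadjusted p under 0.05). With 1 detection limit for all arrays 7 were higher and 21 lower, and with the covariate 39 and 32. The other largest rises were miR-608 (2.71), the miR-638 precursor (2.35), miR-672 (2.33), the miR-600 precursor (2.21), miR-17* (2.11), miR-137 (1.82), the miR-433 precursor (1.75), miR-186 (1.36, with its mean of 5.75 under the limits of the 2 control arrays at the floor) and the Plus/Minus probe of miR-138-1* (0.98), whose other probe stood at 0.01 (adjusted p = 0.989). Of the 12 named rises, 9 were at the floor on 2 of 3 control arrays (miR-125b-2*, miR-451, miR-608, miR-672, miR-17*, miR-137, miR-186 and the precursors of miR-638 and miR-600), so their sizes depend on where the floor lies. The other largest falls were the miR-128a precursor (-2.17), miR-603 (-1.89), the miR-194-1 precursor (-1.29), miR-24 (-1.15), miR-16 (-1.12), miR-212 (-0.80) and miR-106b (-0.75). The first 3 of these were at the floor on 4, 5 and 8 of 12 POL6326 arrays, so their sizes depend on it as well. By list, the neural list had 2 higher and 2 lower, the stem-cell list 1 higher and 2 lower, the miR-17 list 1 higher and 1 lower, the DLK1-DIO3 cluster 2 higher, the NF-kB-linked, erythroid and let-7 lists 1 higher each, the miR-15 and miR-16 family 2 lower (miR-15b and miR-16), the p53-linked, HOX-embedded and myeloid lists 1 lower each, and 0 passed in the others. Adjusted over the list alone, the neural list had 4 higher and 3 lower, the NF-kB-linked list 3 higher and 2 lower, the miR-15 and miR-16 family 1 higher and 2 lower, the HOX-embedded and myeloid lists 2 lower each, and the muscle and stromal lists 1 lower each. Camera put 0 of 17 lists past the threshold (lowest adjusted p = 0.279, and 0.249 with an estimated correlation). By fry the myeloid list was lower on balance (median -0.12, adjusted p = 0.0187), with miR-24 the 1 member past the threshold, and with quantile normalization this ended (median -0.04, adjusted p = 0.103). Without control array 1, 44 probes passed, and with the covariate 71 did, which included all 29. The miR-600 precursor, miR-17*, miR-137, the miR-433 precursor, miR-136*, the miR-128a precursor, miR-603, miR-24, miR-16 and miR-106b each lost their call without at least 1 of the 3 control arrays.

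At single times, POL6326 and control differed in 37 probes at 1 h (18 higher, 19 lower with POL6326), 33 at 2 h (17 and 16), 34 at 4 h (13 and 21) and 24 at 8 h (15 and 9), with 131, 131, 144 and 121 at an unadjusted p under 0.05. miR-125b-2* rose by 3.49 (SE 0.28) at 1 h, by 3.19 (SE 0.28) at 2 h and by 2.71 (SE 0.28) at 8 h, and differed by 0.54 (adjusted p = 0.252) at 4 h. miR-496 rose by 2.69 (SE 0.60) at 1 h and 3.14 (SE 0.60) at 2 h, when miR-146a, an inflammation-linked miRNA, rose by 3.35 (SE 0.58) and miR-451 by 3.25 (SE 0.43). At 1 h miR-187 was at least 5.58-fold, the miR-646 precursor at least 4.75-fold and miR-603 at least 4.06-fold lower, and at 2 h the miR-128a precursor was at least 4.58-fold lower. miR-572 fell by 3.80 (SE 0.61) at 2 h, 2.83 (SE 0.61) at 4 h and 2.62 (SE 0.61) at 8 h. At 4 h miR-16 fell by 2.63 (SE 0.39), miR-181a-2* by 2.36 (SE 0.50), miR-140-3p by 2.08 (SE 0.42) and miR-454 by 1.97 (SE 0.52). At 8 h the miR-638 precursor (3.49, SE 0.59), miR-17* (3.08, SE 0.71), miR-672 (2.59, SE 0.61) and miR-203 (2.33, SE 0.52) rose and miR-425 fell by 1.46 (SE 0.34). The rises named at these times, miR-496 apart, were of probes at the floor on 2 of 3 control arrays, so their sizes depend on where the floor lies. Without control array 1 the 4 h count was 193 and without control array 2 it was 7, and it was 58 with median centring. At 8 h it was 244 with median centring (20 higher, 224 lower), 179 of these at the floor on over 50% of arrays, and 46 with the covariate. With 1 detection limit for all arrays 9 were higher and 20 lower at 2 h, and 11 and 18 at 8 h. The 1 h count was 7 when only the groups compared were fitted and 14 without control array 2, which also took the 8 h count to 11.

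**Figure D4:**
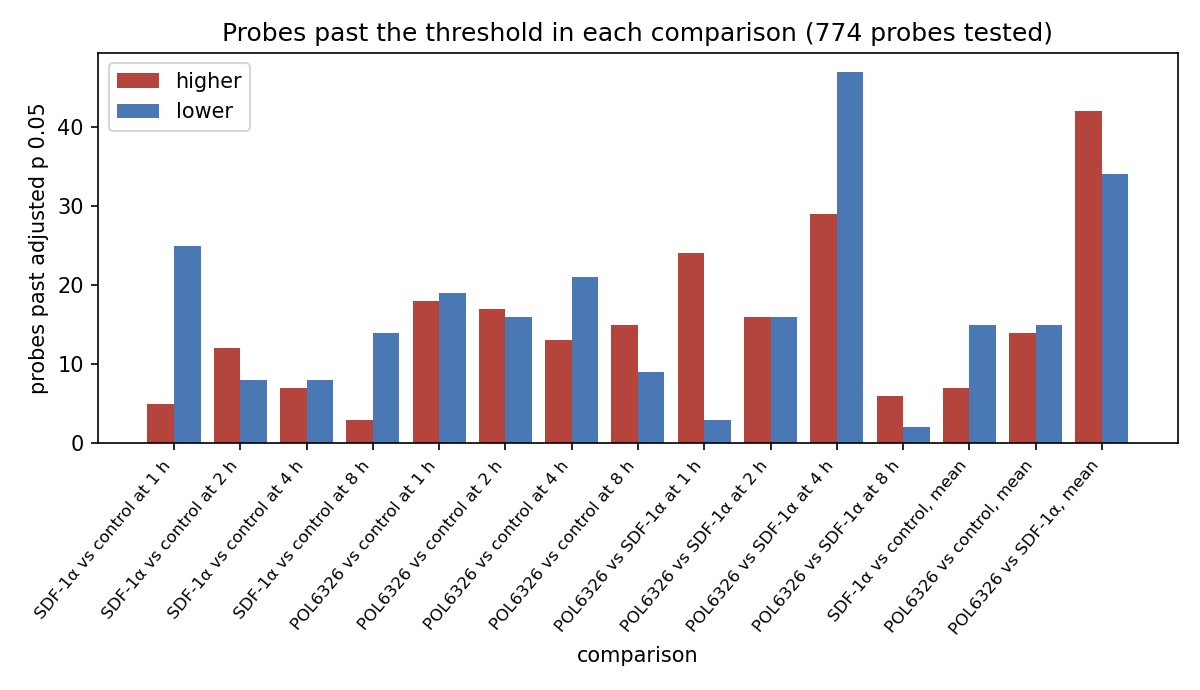
Number of probes past adjusted p 0.05 that were higher (red) or lower (blue) in each of the 15 comparisons; mean stands for the mean of 4 times. The bars are highest for POL6326 vs SDF-1α at 4 h, with 29 higher and 47 lower, and for its mean, with 42 higher and 34 lower.

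Both treatments were compared with the same 3 control arrays. They shared 2 rises against it (miR-125b-2* and the miR-433 precursor) and 7 falls (miR-10a, miR-128a, miR-15b, the miR-194-1 precursor, miR-212, miR-30b and miR-30c), and 0 probes were called in opposite directions. Both treatments were sampled later than the control, so shared changes may reflect time in culture. In 100 simulations of unchanged groups against 1 shared control group, the shared calls averaged 0.01 higher (at most 1) and 0.04 lower (at most 2). As no probe changes in them, few are called at all, so they cannot judge the 9 shared calls. The log2 changes of the 774 probes correlated across probes at r = 0.69, inside the simulated range of 0.57 to 0.94, and probes are not independent replicates. Their covariance was 0.242, above the simulated range of 0.0354 to 0.199. Of the 9 shared probes, miR-125b-2* was 1.50 higher (adjusted p = 1.53e-06), although it was 1.04 lower at 4 h (log2 -1.04, adjusted p = 0.0284) and bounded at 1 h to at least 1.72-fold higher, and miR-30b was 0.42 lower (log2 -0.42, adjusted p = 0.0284) with POL6326 than with SDF-1α.

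Over time within SDF-1α, 44 probes changed by limma's moderated F-test. miR-758 went from the floor at 1 h (4.41 ± 0.03) to 8.39 ± 0.31 at 2 h, 9.26 ± 0.31 at 4 h and 8.71 ± 0.61 at 8 h (SD, n = 3 each; adjusted p = 2.78e-08 by limma), and was 8.57 ± 0.44 in control. miR-557 was at the floor at 1 h too and read 6.94 ± 0.20, 7.93 ± 0.56 and 7.66 ± 0.67 later (SD, n = 3 each). The mean detection limit at 1 h was 7.16, above the 2 h value, so no rise from 1 to 2 h is shown for it. miR-196b was above the floor on all 3 arrays at 2 h (6.72 ± 0.22), miR-380* at 4 h (6.72 ± 0.22) and miR-652 at 8 h (5.27 ± 0.37), values that lie under the mean limit at 1 h. Over time within POL6326, 105 probes changed. miR-191, a highly abundant miRNA of blood cells, was 14.47 ± 0.15 at 1 h, 12.90 ± 0.21 at 4 h and 13.56 ± 0.15 at 8 h (SD, n = 3 each; adjusted p = 0.000299 by limma), and the miR-212 precursor rose from 9.54 ± 0.24 at 1 h to 10.67 ± 0.21 at 4 h. miR-125b-2* dipped from 7.94 ± 0.04 at 1 h to 4.99 ± 0.20 at 4 h and was 7.16 ± 0.14 at 8 h, miR-493 read 5.88 at 4 h, and miR-19a* read 5.01 at 8 h, where these 2 probes were above the floor on 6 and 7 of 27 arrays. The mean POL6326 limits at 1 h (5.21) and 2 h (5.34) lie above that 5.01, so no rise of miR-19a* from these times is shown. With values under the floor raised to it 224 probes changed with SDF-1α, 148 of them at the floor on over 50% of arrays. Without the 1 h arrays 18 changed with SDF-1α, and without the 4 h arrays 30 changed with POL6326. With the covariate 34 changed with POL6326.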

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

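Of the tests in this part, those on the share of higher probes at 1 h and on the low-limit arrays for the mean of 4 times were chosen after the results were seen, and so was the common detection limit. The difference between POL6326 and SDF-1α changed with time for 30 probes by limma's moderated F-test of the interaction. The 5 smallest adjusted p by limma belonged to miR-125b-2* (6.52e-06), miR-758 (1.91e-05), miR-557 (0.000687), miR-652 (0.000989) and miR-196b (0.00268). miR-125b-2* was 7.94 at 1 h and 4.99 at 4 h with POL6326, and 6.03 at 4 h with SDF-1α. At 1 h it was at the floor on all 3 SDF-1α arrays, whose mean detection limit of 7.16 lies above that 6.03, so no rise with SDF-1α after 1 h is shown. miR-758 and miR-557 were at the floor on all 3 SDF-1α 1 h arrays and above it on the other 24 arrays. miR-652 stood out with SDF-1α at 8 h (5.27) and miR-196b with SDF-1α at 2 h (6.72).

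Control probes that the comparisons of miRNAs do not use also differed between groups, by limma adjusted over these 10 probes. With SDF-1α against control, the transfer RNA probes HSTRNL and HUMTRAB differed by -1.30 and -2.26 on the log2 scale (adjusted p = 0.0358 each). Between POL6326 and SDF-1α, GAPDH differed by 0.73 and the transfer RNA probe HUMTRV1A by -0.70 (adjusted p = 0.0317 each).

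The first pattern weighed is that of 27 probes called between POL6326 and SDF-1α at 1 h, 88.9% were higher with POL6326. The SDF-1α 1 h arrays had the highest detection limits, and with 1 common limit, applied to 276 probes, 41.7% of the calls were higher. Of the 27 calls, 20 were among these 276 probes, and 90% of them were higher before the limit was applied. With the limit 24 probes were called, 10 of them among the 27. The shares with and without it thus cover largely different probes. The share stayed at 87.5% with the number of probes above the floor as a covariate and at 80.8% with quantile normalization. That number does not overlap between the groups compared, at 210 to 241 with SDF-1α and 318 to 334 with POL6326 at 1 h. Of the 25 probes lower with SDF-1α than in control at 1 h, 13 were at the floor on all 3 SDF-1α arrays, and 30.8% of these 13 stayed lower with the common limit (miR-100, miR-15b, miR-570 and miR-758), while 4 were too dim to be tested with it. A high detection limit of these arrays stays a candidate explanation for the direction of the calls at 1 h. It does not account for the 4 that stayed lower, which in the order given were at least 1.69-fold, 2.49-fold, 2.76-fold and 2.65-fold under control when set against those limits. A loss of miRNA signal after 1 h of CXCR4 activation stays open, since the 3 arrays with the high limits are all of 1 group.

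The second pattern is that POL6326 at 4 h, the group with the lowest limits, had the most calls against SDF-1α (76). Control array 1 and SDF-1α 8 h array 1 also had low limits within their groups. Across the 46 called probes above the floor on all arrays, the 4 h difference correlated at r = 0.844 with control array 1 minus the other control arrays, and at r = 0.641 with SDF-1α 8 h array 1 minus the other arrays of its group. Across 40 such probes the mean difference over 4 times correlated with the control contrast at r = 0.646, and probes are not independent replicates. Array or RNA quality may thus account for part of the 4 h calls, falls of miR-16 and miR-424 included. With the number of probes above the floor as a covariate 9 probes passed at 4 h, 8 of them among the 76. That number was 482 to 593 on the POL6326 4 h arrays and 362 to 381 on the SDF-1α 4 h arrays. As these ranges do not overlap, the covariate can remove a treatment effect as well, and its count cannot tell the causes apart. An effect of POL6326 at 4 h stays open.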

How the results depend on the processing

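The common limit, the covariate, the fits without 1 h or 4 h and the raising of values under the floor were chosen after seeing the data. Of 116 results of named probes in the 3 comparisons of means of 4 times, 106 kept their side of the threshold with median centring, 110 with quantile normalization, 98 with the covariate, 97 when only the groups compared were fitted, 95 without 1 h and 101 without 4 h. With the common limit, 61 of the 79 that it tests kept theirs. The 116 include the let-7 family probes, most of which did not pass to begin with, so these shares overstate how well calls hold. Calls lost were 8 with median centring, 5 with quantile normalization and 16 with the covariate. With only the groups compared 19 were lost, without 1 h 21, without 4 h 15, and with the common limit 14. Of the results past the threshold with the deposited values, 0 changed sign, and single times were not covered. The replicate block gave 79 calls between POL6326 and SDF-1α over 4 times, with 114 of the 116 results as before. Equal replicate numbers had a mean residual r of 0.038 (-0.21 to 0.51), against -0.019 for different numbers, and 16 of 27 arrays were closest to one of their own number, so a pairing stays open.

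Median centring moved the median of all probes by -0.30 and -0.33 for POL6326 against SDF-1α at 4 and 8 h and by -0.14 for their mean, by -0.18 and -0.32 for POL6326 against control at 4 and 8 h, and by 0.11 for SDF-1α against control at 4 h. It gave 58 and 244 calls for POL6326 against control at 4 and 8 h, 318, 208 and 310 for POL6326 against SDF-1α at 4 h, 8 h and over 4 times, 14 for SDF-1α against control over 4 times, 405 for POL6326 over time and 226 for the interaction. Of the 310, 195 were at the floor on over 50% of arrays. On arrays with under 50% of probes above the floor, the median was the floor itself. On the POL6326 8 h arrays it lay above the floor (4.73 to 4.77), and likewise at 4 h (4.53 to 4.68). Centring thus moved probes at the floor down on these arrays against the others. Quantile normalization gave 9 for SDF-1α against control at 4 h. With fewer probes tested, the upper 50% by signal gave 46 (SDF-1α, 1 h), 5 (POL6326 against SDF-1α, 8 h) and 47 (interaction), and leaving out dim probes gave 50 and 5 for the first 2.

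Fitted on the groups compared alone, with fewer arrays to estimate the spread, limma called 16, 13, 2 and 0 for SDF-1α against control at 1, 2, 4 and 8 h and 6 over 4 times, 7, 21 and 8 for POL6326 against control at 1, 2 and 4 h, and 0 for POL6326 against SDF-1α at 8 h. With all groups, 101 and 82 reached an unadjusted p under 0.05 where it called 0. With the 299 values under the floor raised to it, 178 were called for SDF-1α against control at 1 h and 224 for SDF-1α over time, and 114 of the 116 results kept their side. The common limit gave 33 (SDF-1α, 8 h), 38 (SDF-1α, mean), 5 (POL6326 against SDF-1α, 8 h) and 47 (interaction).

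With the covariate the counts were 9 and 31 for SDF-1α against control at 1 and 8 h, 46 and 71 for POL6326 against control at 8 h and over 4 times, 9, 14 and 39 for POL6326 against SDF-1α at 4 h, 8 h and over 4 times, 34 for POL6326 over time and 50 for the interaction. let-7a was 1.25 (adjusted p = 0.0878). Without 1 h the counts were 11 for SDF-1α against control and 18 for SDF-1α over time, and let-7a was 1.22 (adjusted p = 0.125). Without 4 h they were 45 for POL6326 against control, 44 for POL6326 against SDF-1α and 30 for POL6326 over time. The causes of these shifts were not tested, except where stated.

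Leaving out 1 array at a time, with the remaining arrays of that group assumed to vary like the others, gave for SDF-1α against control 7 to 153 calls at 1 h (control arrays 2 and 3), 1 to 29 at 2 h (SDF-1α array 2, control array 3), 2 to 20 at 4 h (SDF-1α array 3, control array 3), 7 to 33 at 8 h (SDF-1α arrays 3 and 1) and 3 to 38 over 4 times (control arrays 2 and 3). For POL6326 against control it gave 14 to 45, 23 to 46, 7 to 193 (control arrays 2 and 1), 11 to 28 and 22 to 44. For POL6326 against SDF-1α it gave 11 to 28, 17 to 27, 26 to 72 (lowest without POL6326 array 1), 6 to 12 and 58 to 90. The time tests gave 31 to 177 for SDF-1α, 56 to 97 for POL6326 and 22 to 43 for the interaction. Signal over background limits all of these: 174 of 774 probes were above the floor on every array.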

Other observations

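The tests of let-7a without the 1 h arrays and of cross-hybridisation were chosen after the results were seen. With SDF-1α against control, 3 mature probes were higher and 13 lower of 637, and 4 precursors were higher and 2 lower of 137. With POL6326 against control, the counts were 10 and 12, and 4 and 3. Between POL6326 and SDF-1α they were 36 and 27, and 6 and 7.

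Single-time tests of lists by camera, which include probes at the floor, put 6 past an adjusted p of 0.05, all between POL6326 and SDF-1α. At 1 h these were the let-7 family (2 higher of 17, median 0.29, adjusted p = 0.042, and adjusted p = 0.245 with an estimated correlation), the miR-29 family (median 0.88, adjusted p = 0.042, and adjusted p = 0.108 with an estimated correlation), the neural list (4 higher of 18, adjusted p = 0.0302, and adjusted p = 0.108 with an estimated correlation) and C19MC (median -0.07, 0 with median centring, adjusted p = 0.0302, and adjusted p = 0.518 with an estimated correlation). For C19MC this compares floors (4.34 and 4.41), as 2 of its 50 probes were above the floor on over 50% of arrays. At 2 h it was the HOX-embedded list (2 lower of 11, adjusted p = 0.038, and adjusted p = 0.352 with an estimated correlation), and at 8 h the miR-17 family and clusters (median 0.19, -0.14 with median centring, adjusted p = 0.00783, and adjusted p = 0.187 with an estimated correlation). The title of the series names let-7a, so the family is not an independent choice.

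A miRNA with a Plus/Minus probe beside its ordinary probe formed 34 pairs. Between POL6326 and SDF-1α, miR-138 differed by 3.31 and its Plus/Minus probe by -0.19, miR-126* by 1.81 and 0.22, miR-133b by 1.41 and 0.03, miR-24 by -0.79 and -0.30, and miR-214 by 0.26 and -0.07, with the ordinary probe alone past the threshold. The miR-138-1* pair was called in opposite directions (-0.25 and 0.66). What the Plus/Minus probes detect is not given in the sources used here.

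The third pattern weighed is let-7a, fitted as 1.79 higher with POL6326 than with SDF-1α (SE 0.40). That size depends on where the floor lies, as 4 of 12 SDF-1α arrays were at it. Without the 1 h arrays, where SDF-1α had the high limits, the difference was 1.22 (SE 0.46). This argues against the limit as the whole cause, although the call ended (adjusted p = 0.125) as the difference shrank and its mean covered fewer times. The 1 h arrays still entered the estimate of the spread. The highest adjusted p without any 1 array was 0.0162 over 24 fits, which argues against 1 deviating array. Cross-hybridisation within the family stays open. The 7 other unstarred let-7 probes had a median difference of 0.0985. Resampling these 7 probes gave that median an SD of 0.192, which is a spread between probes and not an error over arrays. However, let-7c stood at 0.70 (SE 0.28) and let-7f at 0.66 (SE 0.35). Array quality stays open, as does an effect of CXCR4 blockade or activation, and neither treatment alone was shown to differ from control.

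Splits of the samples gave as many calls as the real ones in few cases. With 10 splits per single-time comparison the smallest share is 0.1. The real split and the highest other gave, for SDF-1α against control, 30 and 5 at 1 h, 20 and 2 at 2 h, 15 and 2 at 4 h, and 17 and 32 at 8 h, where 2 of 10 splits had as many. For POL6326 against control they gave 37 and 3, 33 and 1, 34 and 36 at 4 h, where 2 of 10 had as many, and 24 and 2. For POL6326 against SDF-1α they gave 27 and 4, 32 and 1, 76 and 1, and 8 and 3. The split with 32 put SDF-1α 8 h array 1 with control arrays 1 and 2, and the split with 36 put control array 1 with POL6326 4 h arrays 1 and 2. Among 100 splits, only the real 1 had as many for POL6326 against control (29, highest other 19), POL6326 against SDF-1α (76, highest other 9), SDF-1α over time (44, highest other 9), POL6326 over time (105, highest other 35) and the interaction (30, highest other 3). This does not exclude chance. For the comparisons with control and the interaction, arrays were shuffled across times, so differences between times widen the spread within a split and can lower its count. Chance differences between cultures are not excluded, as the arrays of a group may not be separate cultures. For SDF-1α against control, 3 of 100 had as many (22), and the 2 others gave 30 and 49. Both placed control array 1 and SDF-1α 8 h array 1, which have low detection limits, together as controls, which points to a structure among the arrays.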
